A study of Nematostella vectensis with 16 samples.

How the data were processed

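Whole-animal RNA was sequenced from 16 pools of Nematostella vectensis in 5 groups: 4 untreated control pools and 3 pools of 5 anemones for each of 4 metals at 100 µg/L for 24 h. The animals were 2 to 4 months old and were kept at 18 °C in artificial seawater of 12.5 ppt in the dark, per the labels' protocols. Total RNA was extracted with Tri-reagent and libraries were made with the TruSeq mRNA kit, per the labels' protocols. Strand, read length and sequencing batch are not given in the sources used here. The submitters' processing notes name STAR, Partek and DESeq with no version or role, and the genome build is not given in the sources used here. Each pool is a separate group of animals per the labels, and p-values measure the spread between pools.

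The authors deposited a table per metal, each with 27273 gene models. Each table holds raw counts per gene model for the 4 control libraries and the 3 libraries of its metal, as whole numbers that the authors had not normalized. Control counts were the same in all 4 tables and were used once. Per the file headers the tables also give base means per group, a normalized signal that lay within 0.01 of the mean of counts divided by median-ratio size factors. The authors' fold change is the ratio of the base means, and the authors' p-values and adjusted p-values stand beside it. In the Cd table the deposited adjusted p-value, treated as a score, exceeded 1 for 930 genes (up to 3977), all 930 of them with a fold of 0. In the authors' deposited table for Hg 1586 genes were higher and 615 lower at an adjusted p under 0.05, and 2163 of these 2201 genes were also called here. In the authors' deposited tables the other metals had 280 higher and 41 lower for Cu, 7 and 1 for Cd and 6 and 2 for Zn. Calls made here that the authors' deposited tables share numbered 286 for Cu, 2 for Cd and 1 for Zn. All other values were computed from the counts, and every column of per-library counts was used.

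Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the default filterByExpr rule, which left 16276, and libraries were scaled by TMM factors. All 16 libraries entered one quasi-likelihood fit with robust dispersion and one term per group, with no replicate block. Each metal was tested against control and each of the 6 metal pairs against each other, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of its F statistic. CPM values use the TMM-scaled library sizes, and mean ± SD are over the pools of a group. Ratios of summed counts carry exact 95% intervals that cover counting error only. The median log2 fold change over all tested genes was -0.05 in Hg and -0.02 in Cu. The fit was tested on simulated counts for the 16276 genes, with 54 to 75 genes changed at each fold in each metal. At 2-fold it recovered 60.3% of changed genes for Hg, 52.9% for Cu, 52.5% for Cd and 54.9% for Zn, at 1.5-fold 20.6%, 23%, 16.2% and 25.9%, and at 4-fold 89.9%, 85.7%, 87.3% and 84%. It called 4 to 7 unchanged genes per metal.

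Depth was 5494659 to 8113825 counts per library, so that a gene at 1 CPM had about 5 to 8 counts per library. In Hg 11.7% of genes were called among the lowest of 3 equal parts by mean CPM, 26.4% in the middle and 41.8% in the highest.

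The gene identifiers were looked up in a table of 38762 genes of assembly jaNemVect1.1, and 0 matched, so the files do not pair them with names. The 27 gene lists planned before the data were examined, among them metal-binding, heat shock and antioxidant lists, could not be tested for that reason, and no gene is described by function. Named genes followed a rule fixed before the data were examined. Among called genes with at least 1 CPM in the higher group and all metal libraries beyond all control libraries, those with the largest fold change were taken, at most 2 each way per metal because none has a description. Genes called in all 4 metals were added. Counts of 5 or fewer genes were also named, after their values were seen.

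Module 1 was found from the deviations of log2 CPM (prior count 2) from the group means. Its first principal component held 24.8% of the variance, and the module holds genes with a correlation above 0.8 to the gene with the largest loading and an SD above 0.5. For module 2 the gene with the largest loading was found after removing the difference between the 2 library sets that module 1 defines. Its other genes were chosen from the deviations from group means, as in module 1. Module 3 was chosen in the same way around v1g216383, the called gene with the lowest fitted fold change in Hg. These sets were defined from the data and are not groups of the study. Similarity between metals was compared with 20 simulations of unchanged libraries, and with the 4 controls split into pairs in all 3 ways, giving 6 assignments per metal pair.

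Alternatives planned before the data were examined were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, a mean CPM of at least 5, fits with only the groups compared, the replicate number as a block, leaving out each library, a minimum change of 1.5-fold and an adjusted p under 0.01. Alternatives for tables without counts did not apply. Alternatives added after the data were seen were the library set as a term, the 10 libraries with low module 1 alone, controls 1 and 2 alone, and the 3 modules left out. Reading calls from one library set in the other was also added then.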

Results

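Transcript levels were measured by RNA sequencing in whole starlet sea anemones, Nematostella vectensis, a small estuarine cnidarian kept as a laboratory animal. Pools of anemones aged 2 to 4 months, 5 per metal pool, were held for 24 h in artificial seawater with the chloride of mercury (Hg), copper (Cu), cadmium (Cd) or zinc (Zn) at 100 µg/L, and untreated pools served as controls. Each metal group held 3 pools and the control group 4, which gave 16 libraries. Raw counts over all gene models summed to between 5494659 and 8113825 per library, both of these in the Hg group, and to between 5517015 and 7643452 in the controls. Replicate pools differed by more than counting error, with a chi-square per degree of freedom of 4.94 to 14.1, and no library was a copy of another. Of 27273 gene models, 3705 had no count in any library and 16276 passed the filter on low counts. The biological coefficient of variation between pools of one group was 16.7%. Gene models carry identifiers that the files do not pair with gene names or functions, so changes are described by number, size and overlap, and few genes are named by identifier.

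Libraries of one group also differed in sets of genes that moved together. The levels of 198 genes (module 1) summed to between 1470 and 2680 CPM (counts scaled to library size) in controls 1 and 2, Hg 3, Cu 3, Cd 1 and Zn 3, and to between 308 and 670 CPM in the other 10 libraries. They were chosen for varying between pools of one group, and none was called against control in any metal (edgeR). A set of 20 genes (module 2) summed to 693 to 4150 CPM in controls 3 and 4, Hg 3 and Cd 2, against 16.7 to 143 CPM elsewhere. A set of 60 genes (module 3) summed to 291 to 849 CPM in controls 3 and 4 and Cu 3, against 41.8 to 62.2 CPM in the other libraries. The labels give no batch, day or sex for the pools.

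**Figure D1:**
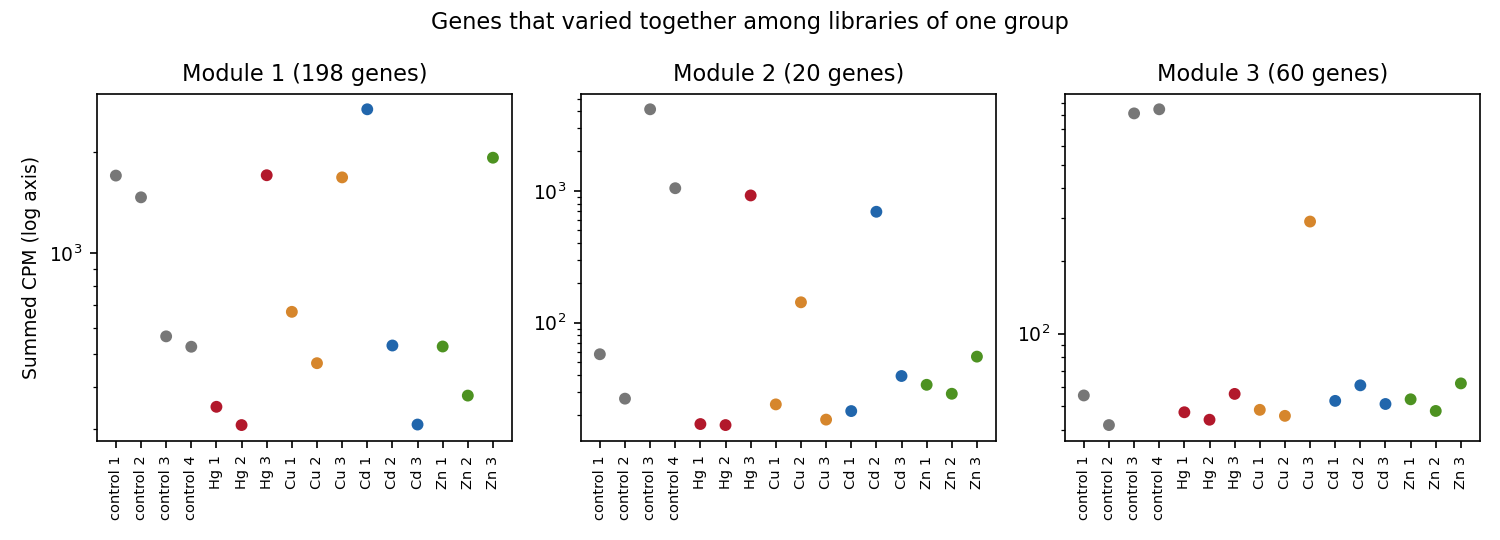
Summed CPM (vertical, log axis) of the genes of modules 1, 2 and 3 in each of the 16 libraries, one point per library coloured by group. Module 1 was high in 6 libraries that include all 5 groups, and module 3 was high in controls 3 and 4 and Cu 3.

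The comparison of each metal with control asked which transcripts changed after 24 h. Mercury gave the most calls. In Hg pools 2439 genes rose and 1897 fell against control, together 26.6% of the 16276 genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change was 0.76 for genes that rose and -0.69 for genes that fell. Changes of at least 2-fold were found for 821 genes that rose and 475 that fell, and changes of at least 8-fold for 41 and 33. The genes that rose took 12.2% ± 0.76 (SD, n = 4) of all counts in controls and 23.6% ± 0.83 (SD, n = 3) in Hg pools. The genes that fell took 20.1% ± 0.62 (SD, n = 4) in controls and 13.7% ± 0.35 (SD, n = 3) in Hg pools. Over all tested genes the Hg and control libraries did not overlap for 32.1%, where chance gives 5.71%.

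The pair of called genes with the largest increases in Hg were v1g210079 and v1g127536. v1g210079 measured 52.4 ± 6.8 CPM (SD, n = 3) in Hg pools and 0.211 ± 0.16 CPM (SD, n = 4) in controls. Its log2 fold change was 7.88 ± 0.38 (SE), with an edgeR adjusted p of 8.89e-11. For v1g127536 the means were 23 ± 2.6 CPM (SD, n = 3) and 0.0764 ± 0.088 CPM (SD, n = 4). The controls held 2 counts of it and the Hg pools 473, a ratio of 285 after scaling to library size (95% counting interval 78.3 to 2360, edgeR adjusted p = 5.91e-08). The called pair with the largest decreases were v1g216383 and v1g205550. The Hg pools held 1 count of v1g216383 and the controls 199, a ratio of 165 between controls and Hg (95% counting interval 29.3 to 6560, edgeR adjusted p = 0.0327). The Hg pools held 1 count of v1g205550 and the controls 125, a ratio of 104 (95% counting interval 18.3 to 4140, edgeR adjusted p = 0.0258).

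Both genes belong to module 3, and their control counts lay in controls 3 and 4. Control 3 had 16.7 CPM and control 4 had 16.9 CPM of v1g216383, against 0.724 CPM in control 1 and 0.161 CPM in control 2. Its fitted log2 fold changes were -6.22 in Cd, -7.02 ± 2.17 (SE) in Zn and -2.33 in Cu, against -6.98 ± 2.18 (SE) in Hg. It was not called in Cd, Zn or Cu (edgeR adjusted p = 0.592, 0.609 and 0.427). Adjusted p-values also depend on how many other genes changed in the same metal. The call in Hg thus does not set Hg apart from Zn in this gene. Among the Cu pools Cu 3 alone held counts of it, at 4.78 CPM. Leaving out any 1 Hg library ended the calls of both genes in Hg, with fitted log2 fold changes of -8.80 to -6.54 for v1g216383 and -8.13 to -5.88 for v1g205550. Neither was called without a filter on low counts or in the test for a minimum change of 1.5-fold. The authors' deposited values for Hg also called neither. Of the 60 module 3 genes, 27 were called lower in Hg, among them 21 of the 33 genes that fell at least 8-fold. Module 3 was built around v1g216383, which was picked for its fall in Hg, so this overlap follows in part from that choice. In these 21 genes controls 1 and 2 lay a median of 0.52 log2 units above the Hg pools and controls 3 and 4 a median of 4.71 above, and in the other 12 genes the medians were 2.67 and 3.12. With controls 1 and 2 alone, a setting chosen after the data were seen, 1888 of the 2439 genes that rose in Hg were called again, and 1058 of 1878 genes that fell. Of the 27 module 3 genes, 11 could be tested in that setting, of which 10 were lower in Hg and 0 were called. Genes called in Hg from the 10 libraries with low module 1 alone were read in the libraries with high module 1, which had no part in those calls but hold only 1 Hg pool (Hg 3) against controls 1 and 2. There 95.9% of 2062 genes called higher were also higher and 89.5% of 1428 called lower were also lower, against 43% and 57% of uncalled genes.

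**Figure D2:**
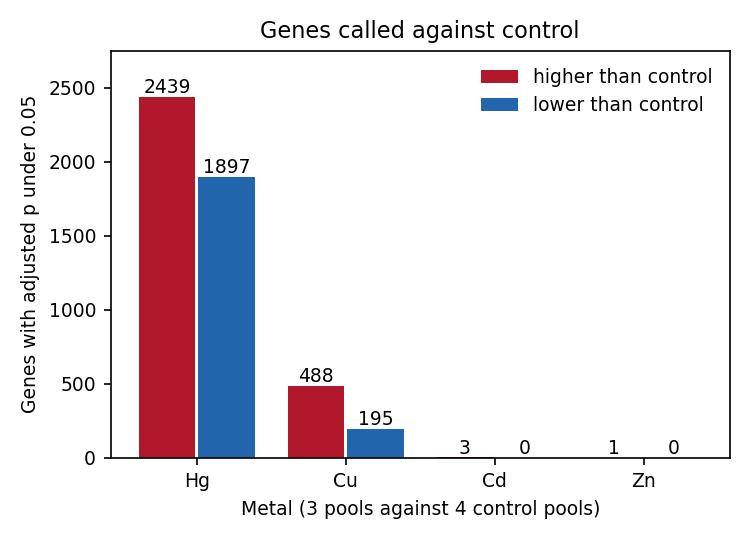
Number of genes (vertical, from 0) with edgeR adjusted p under 0.05 in each metal against control, with genes higher in red and genes lower in blue. Hg gave 2439 and 1897 genes, Cu 488 and 195, Cd 3 and 0, and Zn 1 and 0.

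Copper gave fewer calls than mercury. In Cu pools 488 genes rose and 195 fell (edgeR, same threshold), 4.2% of those tested, with median log2 fold changes of 0.68 and -0.77. Of these, 137 rose and 52 fell at least 2-fold. The genes that rose took 3.18% ± 0.17 (SD, n = 4) of counts in controls, 5.57% ± 0.27 (SD, n = 3) in Cu pools and 8.06% ± 0.1 (SD, n = 3) in Hg pools. The same pair of called genes had the largest increases in Cu. v1g127536 reached 3.6 ± 2.2 CPM (SD, n = 3) in Cu, a ratio of 43.5 to the 2 control counts (95% counting interval 11.6 to 367, edgeR adjusted p = 0.000562). v1g210079 reached 7.2 ± 2.3 CPM (SD, n = 3), with a log2 fold change of 5.02 ± 0.47 (SE) and an edgeR adjusted p of 3.15e-06. Among called genes whose Cu libraries all lay below all controls, v1g59063 fell most. It went from 3.43 ± 0.99 CPM (SD, n = 4) in controls to 0.324 ± 0.17 CPM (SD, n = 3) in Cu, a log2 fold change of -3.34 ± 0.45 (SE) (edgeR adjusted p = 0.000168). It fell in Hg as well, with a log2 fold change of -2.31 (edgeR adjusted p = 0.000203), while its Cd and Zn means were 3.25 and 4.28 CPM. v1g236715 had 13.7 ± 11 CPM (SD, n = 4) in controls and 1.78 ± 1.1 CPM (SD, n = 3) in Cu (log2 fold change -2.96 ± 0.73 SE, edgeR adjusted p = 0.0415). Control 3 alone had 29.6 CPM of it, and without that library the log2 fold change was -2.25 and no longer called. Leaving out control 4 or any 1 Cu library also ended the call, at values down to -3.32.

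Of genes called in Cu from the libraries with low module 1 alone, 94.2% of 413 called higher were also higher in the 1 Cu pool with high module 1 (Cu 3) against controls 1 and 2, and 72.3% of 452 called lower were also lower, against 47.2% and 52.8% of uncalled genes. The number that fell in Cu rested on single libraries. It was 296 without control 2, and 69, 52, 75, 64 and 73 without Cu 1, Cu 2, Cu 3, control 3 and control 4. The number that rose was 304 without Cu 2. With controls 1 and 2 alone 304 rose and 26 fell, and in the 10 libraries with low module 1, a setting chosen after the data were seen that leaves out Cu 3 and controls 1 and 2, 413 rose and 488 fell.

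Cadmium gave 3 genes that rose and 0 that fell (edgeR). At an unadjusted p under 0.05 there were 1144 genes, 7.03% of those tested, and DESeq2 called 19 higher and 3 lower. The 3 genes were v1g39805, v1g28119 and v1g167250, and all 3 also rose in Hg and in Cu. Independent lists would share 0.45 genes between Cd and Hg and 0.0899 between Cd and Cu. With the controls split between the metals, 0 to 9 genes were called higher in both Cd and Hg and 0 to 6 in both Cd and Cu, depending on the assignment. Genes called lower numbered 0 to 54 in both Cd and Hg and 0 to 1 in both Cd and Cu. v1g39805 went from 13.4 ± 1.6 CPM (SD, n = 4) in controls to 35 ± 5.4 CPM (SD, n = 3), a log2 fold change of 1.39 ± 0.21 (SE) (edgeR adjusted p = 0.0362). v1g28119 went from 29.6 ± 2.4 CPM (SD, n = 4) to 55 ± 6 CPM (SD, n = 3) (log2 fold change 0.89 ± 0.12 SE, edgeR adjusted p = 0.00895), and stood at 85.5 ± 7.7 CPM in Cu and 186 ± 32 CPM in Hg (SD, n = 3). v1g167250 went from 110 ± 9.7 CPM (SD, n = 4) to 170 ± 12 CPM (SD, n = 3) (log2 fold change 0.62 ± 0.09 SE, edgeR adjusted p = 0.0235), with 298 ± 12 CPM in Cu and 703 ± 69 CPM in Hg (SD, n = 3). The count of genes that rose in Cd was 0 without Cd 1, without Cd 2 or without control 3, and 1 without Cd 3 or without control 1. The counts also changed with the libraries used. In the 10 libraries with low module 1, which leave out Cd 1 and controls 1 and 2, 23 genes rose in Cd and 147 fell, and with controls 1 and 2 alone 0 rose and 0 fell (edgeR). In simulated data of the same depth and spread per gene, 52.5% of 61 genes changed 2-fold in Cd were recovered. Of 71 genes changed 4-fold 87.3% were recovered, and 4 unchanged genes were called in Cd. These genes were changed together, and the adjusted threshold is stricter where fewer genes change. Recovery may therefore be lower where as few genes change as were called in Cd. The simulation drew each gene independently and held no library sets, so it does not show recovery where such sets differ.

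Zinc gave 1 gene that rose and 0 that fell (edgeR), with 1145 genes at an unadjusted p under 0.05, 7.03% of those tested. DESeq2 called 6 higher and 1 lower. The 1 gene was again v1g39805, at 39.1 ± 5.5 CPM (SD, n = 3) in Zn (log2 fold change 1.55 ± 0.21 SE, edgeR adjusted p = 0.0261). It was the 1 gene called in all 4 metals with these settings (2 without a filter on low counts or with fits of only the groups compared, 0 with a replicate block, 5 by DESeq2), with 45.8 ± 18 CPM in Hg and 45.3 ± 3.1 CPM in Cu (SD, n = 3), and every one of the 12 metal libraries lay above every control. Leaving out any 1 Zn or control library ended its call in Zn, with log2 fold changes that stayed between 1.43 and 1.64. Leaving out any 1 Cd or control library likewise ended its call in Cd, with values between 1.28 and 1.5. In the 10 libraries with low module 1, which leave out 1 pool of each metal and controls 1 and 2, 28 genes rose in Zn, 223 fell and 133 were called in the same direction in all 4 metals, against 0, 0 and 0 with controls 1 and 2 alone (edgeR). In simulated data without library sets 54.9% of 71 genes changed 2-fold in Zn were recovered, and 7 unchanged genes were called. As for Cd, recovery may be lower where fewer genes change.

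**Figure D3:**
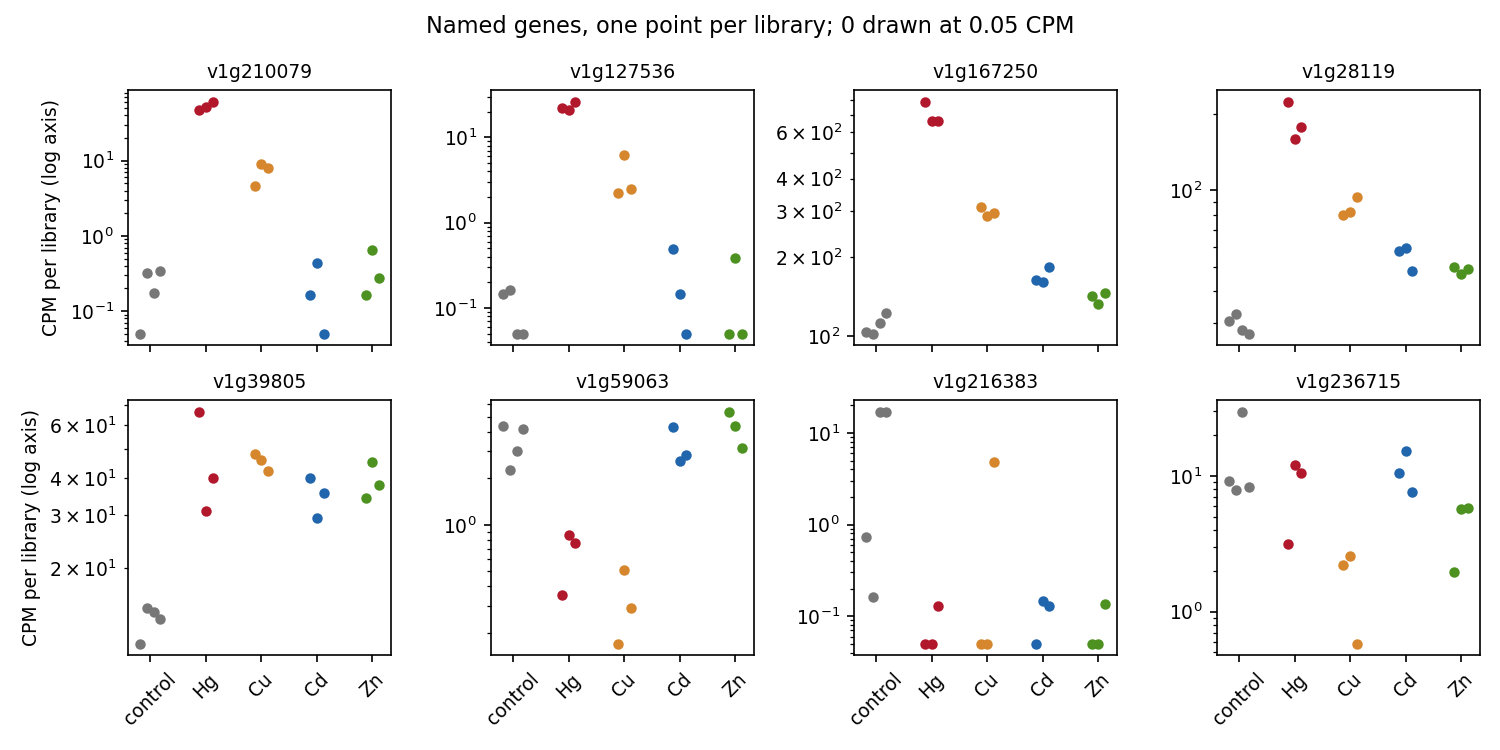
CPM per library (vertical, log axis, with 0 drawn at 0.05 CPM) of 8 named genes by group, one point per library. v1g210079 and v1g127536 were high in Hg and intermediate in Cu, v1g39805 was above control in every metal library, and v1g216383 was high in controls 3 and 4 and Cu 3.

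Whether Hg and Cu changed the same genes was read from their overlap and from the direct contrast. Of the genes that rose in Cu, 452 (92.6%) also rose in Hg, and of those that fell in Cu, 152 (77.9%) also fell in Hg. Independent lists of these sizes would share 73.1 and 22.7 genes. The comparisons share their controls, and in 20 simulations of unchanged groups at most 1 gene was called in any comparison, which leaves 0 in both and does not show what shared controls add to lists of this size. With the controls split so that each metal had its own pair, between 216 and 379 genes rose in both and between 23 and 169 fell in both. The 452 shared genes had a median log2 fold change of 1.34 in Hg and 0.68 in Cu. By the contrast of Hg with Cu, 313 of them were higher in Hg and 0 higher in Cu (edgeR). Among the 152 that fell in both, the medians were -0.97 in Hg and -0.79 in Cu, and 28 were lower in Hg than in Cu. Genes that rose in Cu and were not called in Hg numbered 32, of which 17 were higher in Cu than in Hg by the contrast.

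**Figure D4:**
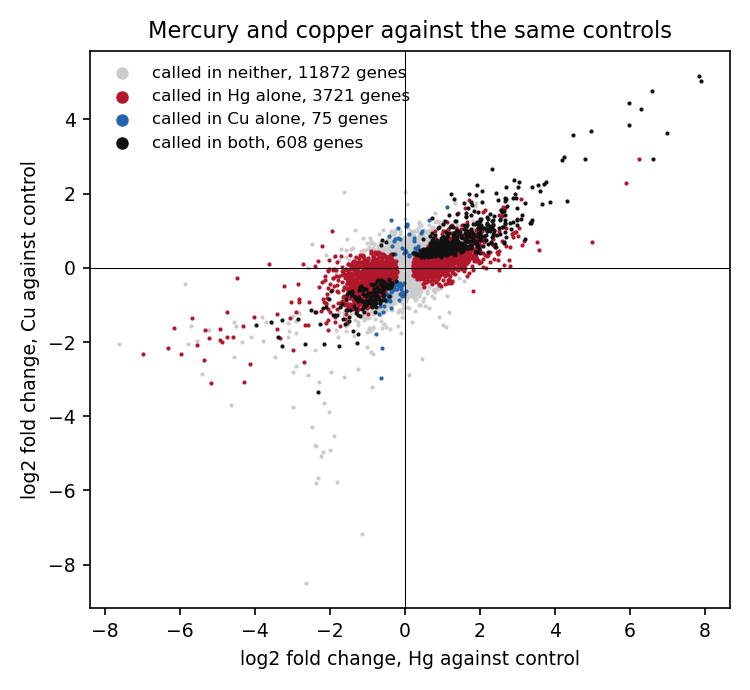
Log2 fold change against control in Cu (vertical) and in Hg (horizontal) of the 16276 tested genes, coloured by the metal in which edgeR called them. The genes called in both lie mostly at upper right and lower left, with 452 higher in both and 152 lower in both.

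The direct contrasts between metals separated Hg from each of the others. Between Hg and Cu 2317 genes were called (edgeR), 1606 of them higher in Hg and 711 lower. Between Hg and Cd 3930 genes were called, 2308 higher and 1622 lower in Hg, and between Hg and Zn 4313 genes, 2480 higher and 1833 lower. Between Cu and Cd 413 genes were called, 352 higher and 61 lower in Cu, and between Cu and Zn 587 genes, 459 higher and 128 lower. Between Cd and Zn 0 genes were called by edgeR and 0 by DESeq2, with 599 genes (3.68%) at an unadjusted p under 0.05. These counts fell by over 1.5 times without some libraries. Hg against Cu gave 1529 without Cu 1. Cu against Cd gave 255 without Cd 1, 258 without Cd 3 and 263 without Cu 2. Cu against Zn gave 338 without Cu 2, 375 without Cu 3, 359 without Zn 2 and 372 without Zn 3.

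Genes called in Hg were next read in the other metals with separate controls, so that no control library served both metals. Genes that rose in Hg against 2 of the controls (1919 to 2168 genes over 6 assignments) had a mean of median log2 fold changes of 0.24 in Cu against the remaining 2, and 82.3% of them were above 0. In Cd the same value was -0.011 with 47.7% above 0, and in Zn it was -0.039 with 41.5% above 0. Genes that fell in Hg had values of -0.178 in Cu, -0.004 in Cd and 0.043 in Zn. Genes that rose in Cu had values of 1.47 in Hg, 0.011 in Cd and -0.018 in Zn.

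Fold changes over all 16276 genes were correlated between metals, with Pearson coefficients across genes, which are not independent replicates, of 0.65 for Hg and Cu, 0.38 for Hg and Cd, 0.33 for Hg and Zn, 0.47 for Cu and Cd, 0.47 for Cu and Zn and 0.68 for Cd and Zn. Unchanged groups simulated against the shared controls gave mean coefficients of 0.42 to 0.44. The covariance was 0.203 for Hg and Cu against 0.0482 in the simulation, and 0.113 for Cd and Zn against 0.0496. The other pairs had covariances of 0.103 (Hg and Cd), 0.102 (Hg and Zn), 0.0792 (Cu and Cd) and 0.0885 (Cu and Zn), where the simulation gave 0.0478, 0.0488, 0.0483 and 0.0482. With split controls the mean coefficients were 0.39 for Hg and Cu, 0.22 for Cd and Zn, and 0.09 to 0.12 for the other 4 pairs.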

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

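The tests on module 3 were chosen after its levels were seen, and those for an exchanged library were changed after results were seen.

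Among 13 control values tested for a library far from the other 3, 1 stood apart. Control 3 had 29.6 CPM of v1g236715, 1 of the pair with the largest decreases in Cu among called genes whose Cu libraries all lay below all controls, where the other controls had 7.88 to 9.12 CPM. Chance marks about 1 in 20 such groups.

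For 4 genes the changes in Hg and Cu went opposite ways, lower than control in Hg and higher in Cu, and the contrast of Hg with Cu was called for each (edgeR). The log2 difference of Hg from Cu was -0.69 for v1g124608 (adjusted p = 0.00021), -1.26 for v1g218117 (adjusted p = 4.02e-05), -1.18 for v1g241424 (adjusted p = 0.000208) and -1.35 for v1g84211 (adjusted p = 3.59e-05). Their log2 fold changes were -0.32, -0.64, -0.50 and -0.61 in Hg and 0.38, 0.62, 0.69 and 0.74 in Cu. The genes were picked after their values were seen. No gene was called higher in Hg and lower in Cu by edgeR.

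The largest decreases in Hg lay mostly in module 3, whose 27 genes called lower had a median log2 fold change of -4.59. In the 21 genes of module 3 that fell at least 8-fold, controls 1 and 2 lay a median of 0.52 log2 units above the Hg pools. Controls 3 and 4 lay 4.71 above, so the size of the fall rested on them. In the 12 such genes outside module 3 the medians were 2.67 and 3.12. These values do not decide whether mercury lowered the 21 genes. Module 3 was chosen for varying within groups with v1g216383, so low levels in controls 1 and 2 follow largely from that choice. Levels there also lay near the floor, where the prior count of 2 narrows log2 differences. An exchange with an Hg or Cu pool is argued against for controls 3 and 4, and with a pool of another group for Cu 3. Their mean level of the genes that rose in Hg differed from the others of their group by at most 0.02 log2 units. Controls lay at 4.55 to 4.58 log2 CPM, Cu pools at 4.85 to 4.94 and Hg pools at 5.49 to 5.55. These genes were called with controls 3 and 4 counted as controls, so for these controls the reading is partly set by the labels. An exchange of control 3 or 4 with a Cd or Zn pool is argued against too, less firmly for control 3. The 17 to 19 genes read were chosen without controls 3 and 4. They were called in both Hg and Cu against controls 1 and 2, and the Cd and Zn pools also lay beyond these controls. Control 4 lay 0.22 to 0.27 of the way from controls 1 and 2 to the Cd and Zn pools, and control 3 lay 0.43 to 0.54. Cd or Zn libraries left out of the choice in turn lay at 0.88 to 1.08. Controls 1 and 2 took part in the choice, so other controls can lie above 0 for that reason alone. Material present in only some pools stays open, because genes chosen without the 2 libraries compared had a median SD of log2 ratios of 0.41 (other genes 0.50) and 2 of the 3 pairs of high libraries lay above other genes.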

How the results depend on the processing

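The library set as a term, the 10 libraries with low module 1, controls 1 and 2 alone and the modules left out were chosen after the data were seen. Of 282 counts of called genes recomputed under these settings and those fixed before the data were examined, 183 lay within 1.5 times the reported count. Of 238 recomputed fold changes of named genes, 178 stayed called, 60 did not pass the threshold and 0 changed sign. The cause of a change was not tested unless given.

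DESeq2 called 19 genes higher and 3 lower in Cd, 6 higher and 1 lower in Zn, and 5 in all 4 metals. A stricter adjusted p under 0.01 left 905 lower in Hg, 264 higher and 36 lower in Cu, 1 higher in Cd, 0 in Zn and 0 in all 4 metals, and in the contrasts 1289 (Hg and Cu), 2449 (Hg and Cd), 2754 (Hg and Zn), 230 (Cu and Cd) and 286 (Cu and Zn), as its construction requires. The test for a minimum change of 1.5-fold left 849 higher and 235 lower in Hg, 84 and 5 in Cu, 0 higher in Cd, 0 in Zn and 0 in all 4, and in the contrasts 387, 1037, 1176, 74 and 91 in that order. Without a filter there were 119 lower in Cu, 3 higher in Zn and 2 in all 4 metals. Fits of only the groups compared gave 74 lower in Cu, 4 higher and 1 lower in Zn and 2 in all 4 metals. DESeq2 size factors in edgeR, a mean CPM of at least 5 and the modules left out kept every count within 1.5 times.

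With the replicate block there were 74 genes lower in Cu, 3 lower in Cd, 0 higher and 2 lower in Zn and 0 in all 4 metals, and no other count moved by over 1.5 times. The numbers did not pair the pools as a whole: deviations of same-numbered libraries correlated at -0.27 to 0.39 (median -0.03). Of 30 pairs 7 lay over 0.1, and 6 of 15 libraries correlated best with their own number. The highest were Hg 3 with Zn 3 (0.39), Cd 1 with control 1 (0.31), Cu 3 with Zn 3 (0.26) and Hg 3 with Cu 3 (0.24). All of these libraries had high module 1.

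The library set as a term gave 370 lower in Cu and 3 higher in Zn. The 10 libraries with low module 1, where the controls are 3 and 4, gave 488 lower in Cu, 23 higher and 147 lower in Cd, 28 higher and 223 lower in Zn, 133 in all 4 metals, 206 between Cu and Cd and 300 between Cu and Zn. Controls 1 and 2 alone gave 1235 lower in Hg, 304 higher and 26 lower in Cu, and 0 higher in Cd, 0 higher in Zn and 0 in all 4 metals. The counts in Cd and Zn thus moved with the libraries kept.

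Leaving out 1 library gave these ranges: Hg 2011 to 2366 higher and 1312 to 1889 lower, Cu 304 to 512 higher and 52 to 296 lower, Cd 0 to 2 higher, Zn 0 to 0 higher, and 0 to 4 in all 4 metals, with 4 without Hg 1, 3 without Hg 2 and 0 without any other single library. The contrasts ranged over 1529 to 2018 (Hg and Cu), 2979 to 3641 (Hg and Cd), 3368 to 3785 (Hg and Zn), 255 to 387 (Cu and Cd) and 338 to 465 (Cu and Zn). Counts of 0 lower in Cd and Zn and 0 between Cd and Zn stayed at 0.

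Correlations of fold changes fell with split controls, which removes the shared libraries but also leaves each metal only a pair of controls. Over the assignments the correlations averaged 0.39 (Hg and Cu, range 0.21 to 0.5), 0.12 (Hg and Cd, -0.07 to 0.25), 0.093 (Hg and Zn, -0.1 to 0.23), 0.087 (Cu and Cd, -0.21 to 0.24), 0.1 (Cu and Zn, -0.19 to 0.27) and 0.223 (Cd and Zn, -0.09 to 0.42). With a mean CPM of at least 5 they were 0.7 (Hg and Cu), 0.231 (Hg and Cd), 0.135 (Hg and Zn) and 0.591 (Cd and Zn). Leaving out 1 library gave 0.579 to 0.693, 0.228 to 0.466, 0.184 to 0.462, 0.41 to 0.613, 0.395 to 0.626 and 0.507 to 0.739 for the pairs in the order of the split values, with the lowest of the last 5 without control 3.

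Tests of the gene lists were not run because no identifier could be paired with a name. In data simulated at the depth, spread and number of these libraries, 16.2% to 25.9% of genes changed 1.5-fold were recovered. There 54 to 74 genes were changed 1.5-fold per metal, beside others with larger changes. The parts of depth and of the number of changed genes in this were not tested.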

Other observations

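The tests on module 1 were chosen after its levels were seen, and those on splits of libraries and on shared controls before, except the count of random groupings with calls in more than 1 metal.

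The genes called lower in both Hg and Cu stood lower in the other metals too when read against the same 4 controls. Their median log2 fold change was -0.31 in Cd, with 86.2% below 0, and -0.28 in Zn, with 77.6% below 0. The genes called higher in both had medians of 0.05 in Cd and 0.01 in Zn. These 4 comparisons share their controls. With separate controls, genes that fell in Cu had a mean of medians of -0.108 in Cd and -0.03 in Zn over the 6 assignments, with ranges of -0.184 to 0.022 and -0.115 to 0.073.

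Other splits of the same libraries were counted beside the real ones. The next highest counts for Hg and Cu came from splits that kept all 3 pools of the metal together, so they held part of the real difference. Splits that parted these pools gave at most 0 higher and 1 lower in Hg, and 65 higher and 1 lower in Cu. Of the 35 splits of 3 and 4 libraries, only the real one gave as many genes in Hg and in Cu. For Hg this was 1 of 35 for the 2439 higher (next 904) and for the 1897 lower (next 1444). For Cu it was 1 of 35 for the 488 higher (next 126) and for the 195 lower (next 127). Each taken alone, chance can be excluded for these at the 5% level. The smallest share possible is 1 of 35, and no allowance was made for testing 4 metals in 2 directions. For the genes higher in Cd chance cannot be excluded, since 2 of 35 splits gave at least the real 3. These were the real one and 1 other with 57. Nor can it for the genes higher in Zn, where 2 of 35, the real one and 1 other with 1, gave at least the real 1. For the counts of 0 lower in Cd and in Zn all 35 splits gave as many, at most 10 and 0. The split with 57 genes set Cd 2, control 3 and control 4 against the rest and points to a structure of the samples, but 0 of these genes belong to module 1, 5 to module 2 and 3 to module 3, so most of it lies outside the 3 modules. Of 100 random groupings of the 16 libraries only the real one (1 of 100) gave a gene called in all 4 metals, with 0 in the others, but none of the 99 others called genes in more than 1 metal, so this cannot show whether chance is excluded. The 6 contrasts between metals have 10 splits each, too few for a share under 0.05. The real counts and the highest of the others were 2317 and 1 (Hg and Cu), 3930 and 0 (Hg and Cd), 4313 and 0 (Hg and Zn), 413 and 0 (Cu and Cd), 587 and 1 (Cu and Zn), and 0 and 0 (Cd and Zn), where all 10 gave as many.

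Module 1 was high in 6 of 16 libraries, and its genes were chosen for varying within groups, so they are no test of an effect of exposure. Library size did not by itself separate high from low libraries. The high library had more counts in 75% of pairs of a high and a low one, and fewer in the rest. Cd 1, with high module 1, had fewer counts (6231582) than Cd 2 (6635550) and Cd 3 (7603413). The share of 75% leaves a partial link to library size open. Whether 1 source of RNA at differing doses accounts for the high module 1 levels stays open too. Genes chosen without the 2 libraries compared had a median SD of log2 ratios of 0.38 (other genes 0.47). In 4 of 15 pairs, all with control 1, the SD lay above that of other genes. No biological explanation was tested, since the design names none. A sequencing or library batch also stays open, because the labels give 0 batch fields.

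Fold changes were correlated between metals that share controls. For Hg and Cu the shared controls are argued against as the whole cause, since with split controls the mean covariance was 0.138 and stayed positive in all 6 assignments. For the other pairs the shared controls cannot be excluded: the means were 0.038 (Hg and Cd), 0.0319 (Hg and Zn), 0.0171 (Cu and Cd), 0.0217 (Cu and Zn) and 0.0455 (Cd and Zn), with negative values when controls 1 and 2 were parted from 3 and 4, on average -0.0155 for Cd and Zn. Unequal shares of the 2 library sets in controls and metals are argued against as the whole cause. With the set as a term and both sets among the controls of each metal, all 4 assignments were positive in each pair. The means were 0.158 (Hg and Cu), 0.0666 (Hg and Cd), 0.0578 (Hg and Zn), 0.0434 (Cu and Cd), 0.0465 (Cu and Zn) and 0.0778 (Cd and Zn). Without the term the same assignments were positive too, with means of 0.166, 0.0675, 0.0638, 0.0433, 0.0503 and 0.076 in that order. The argument rests on how little the term moved these means. Assignments that parted controls 1 and 2 from 3 and 4 had no part in it. A shared effect of Cd and Zn and a further difference of controls 3 and 4 from all metal pools, such as module 3, both stay open and untested.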
